A study of Mus musculus with 18 samples.

How the data were processed

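Total RNA extracted with Trizol from 9 normal mouse prostates and 9 TRAMP tumours was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The values are probe set intensities on a linear scale that the authors made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 combines the perfect match and mismatch probes of a probe set into 1 signal and scales each array by a single factor. In the deposited intensities the 2% trimmed mean was 500 on every array. Such scaling removes overall brightness but no intensity-dependent difference, and it leaves dim probe sets noisy. No detection calls were used here, so a gene was called dim where it lay under the 40th percentile of its array.

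Groups and replicate numbers came from the sample labels. Probe sets were named from the platform table: 34945 of 45101 name 1 gene, 932 several and 9160 none, and 64 are controls. Entrez identifiers of 34741 probe sets matched a mouse gene table of assembly GRCm38.p6, used for names only, and no symbol changed. No genome build is named for the arrays, so no coordinates are given. Of 602 symbols in the fixed lists, 56 had no single-gene probe set here and are not analysed here.

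Log2(signal + 16) was computed with no further normalization. A probe set was kept if above the 40th percentile of its array on at least 9 of 18 arrays, which kept 27292 (60.6%). Each of 12793 genes was represented by its kept single-gene probe set with the highest mean; probe sets of 11 genes past the threshold went in opposite directions. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only) tested each, two-sided, with Benjamini-Hochberg adjustment at 0.05. Where a gene was dim on all arrays of a group, the fold is a bound against the 40th percentile of those arrays. Before use, the code was tested on simulated data with 12793 genes, with the mean and SDs of each gene taken from this comparison. It recovered 60% of 100 genes changed by 1 on the log2 scale and 89% of 100 changed by 2, with 6 false calls of 155. The simulated genes varied independently and far fewer changed than were called in the real data, so these rates need not hold there.

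The comparison fixed before the data were examined was tumour against normal prostate, with 34 gene lists, 33 of which had at least 3 measured genes. Lists were tested with camera (correlation 0.01), camera with an estimated correlation and fry. List scores are means of log2 values over measured members. Exact tests used all 48620 splits of 18 arrays into 9 and 9. Relations between scores used all pairings; arrays were taken as separate clusters where the widest gap between neighbours exceeded 33.3% of the range, a rule set after the scores were seen. Named genes were the 10 largest rises and 10 largest falls among genes whose groups did not overlap, up to 4 genes per list by absolute t, and 22 genes fixed in advance where measured. Values of single genes below the filter were chosen after they were seen, apart from Pbsn and Chga.

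Alternatives fixed in advance were pseudocounts of 1 and 64, no filter or a 60th percentile filter, quantile normalization, centring on the 75th percentile or on housekeeping genes, array weights, an intensity trend with robust eBayes, an exact Wilcoxon test, a test against a 2-fold change, the replicate number as a block, omission of probe sets that can match several transcripts, the mean of probe sets, standardized scores and omission of each array in turn. Added after seeing the data were the technical batch as a block and each batch alone, omission of arrays high in genes of another tissue, the actin ratio as a covariate, seminal vesicle and smooth muscle scores as covariates, and the exact test of list scores. The 3' to 5' ratio compares probe sets at both ends of the actin transcript and grows as RNA degrades: it was 1.71 ± 0.693 (log2) in normal prostate and 1.12 ± 0.507 in tumours (exact permutation p = 0.0589, n = 9 each). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.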

Results

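The series compared gene expression in normal mouse prostate with expression in tumours of the TRAMP mouse (Transgenic Adenocarcinoma of the Mouse Prostate), a strain in which viral oncoproteins expressed from a prostate promoter drive prostate cancer. The labels describe 9 normal prostate samples, taken from ventral and dorsolateral lobes, and 9 TRAMP tumours. Total RNA of each sample was hybridised to 1 Affymetrix array, giving 18 arrays with 45101 probe sets each. Nothing in the labels says that samples of a group came from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision. Values are log2(signal + 16) with SD over 9 arrays, and a fold change on this scale understates the change of dim genes. Where a gene was dim, under the 40th percentile, on 5 or more arrays of a group, "floored" gives the log2 difference with dim values raised to that percentile. Adjusted p-values for genes are from limma over 12793 genes.

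The design poses a single question, how tumours differed from normal prostate. Genes of cell division were higher in the tumours, and genes for secreted products of the prostate were lower. Mki67, the gene of a marker of dividing cells, rose from 7.46 ± 1.29 to 11.82 ± 1.43 (log2 fold change 4.37 ± 0.596 SE, limma adjusted p = 0.000104). Egf, which encodes epidermal growth factor, fell from 12.94 ± 1.06 to 8.54 ± 1.05 (log2 fold change -4.41 ± 0.465 SE, limma adjusted p = 1.99e-05). In all, 1444 genes were higher and 1623 lower, 3067 of 12793 genes at an adjusted p under 0.05. Of these, 674 were higher and 687 lower by 2-fold or more. Among probe sets, 2770 of 27292 were higher and 2588 lower. The 9 values of one group lay entirely above those of the other for 186 of the genes that rose and 119 that fell, where chance puts 0.00411% of genes apart. Genes that rose made up 47.1% of those called, 35.2% when arrays were centred on their 75th percentile and 34.5% when centred on housekeeping genes. With the actin 3' to 5' ratio of each array as a covariate, 1647 genes were called.

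The arrays fell into 2 technical batches, seen in the poly-A spike controls added to RNA before labelling. These controls were bright on 6 normal and 5 tumour arrays (log2 9.84 to 12.5) and dim on 3 normal and 4 tumour arrays (3.86 to 4.65). With the batch as a block 3186 genes were called, and within the first batch alone 2109. Within the second batch limma called 0 genes at 3 against 4 arrays, with 1639 at an unadjusted p under 0.05 where 640 would be expected by chance. That batch held normal prostates 7, 8 and 9 and tumours 6, 7, 8 and 9. Of these, normal prostate 9 and tumours 6, 7 and 8 were high in seminal vesicle genes, as described below.

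The 10 largest rises among genes whose groups lay fully apart included several genes of the mitotic apparatus. Trim59, a ubiquitin ligase family member, was dim on all 9 normal arrays and at least 15.3-fold higher in tumours (limma adjusted p = 1.85e-07). The condensin subunit Ncapg, the kinetochore genes Bub1 and Nuf2, the kinase Melk, the helicase Ercc6l and the noncoding transcript Lockd were also dim on all 9 normal arrays. They were higher by at least 4.53-fold, 4.82-fold, 6.23-fold, 4.79-fold, 3.76-fold and 5.74-fold. Uhrf1, which recruits maintenance DNA methylation, rose from 7.045 ± 0.715 to 11.02 ± 1.21. Cdkn2a, which encodes p16 and p19ARF, rose from 6.50 ± 0.808 to 10.40 ± 0.915 (floored 3.26). Among genes whose groups lay fully apart, the largest falls after Egf were Scd1, a stearoyl-CoA desaturase, at -3.80 ± 0.459 SE, and the receptor gene Gpr83 at -3.28 ± 0.408 SE. Gm5617, Abhd3, the arginase Arg2, the phospholipid enzyme Chpt1, the translation repressor Eif4ebp1, Eci3 and the growth hormone receptor Ghr fell, with log2 fold changes of -2.478 to -2.996 (floored -1.81 for Gm5617 and -2.17 for Eci3).

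**Figure D1:**
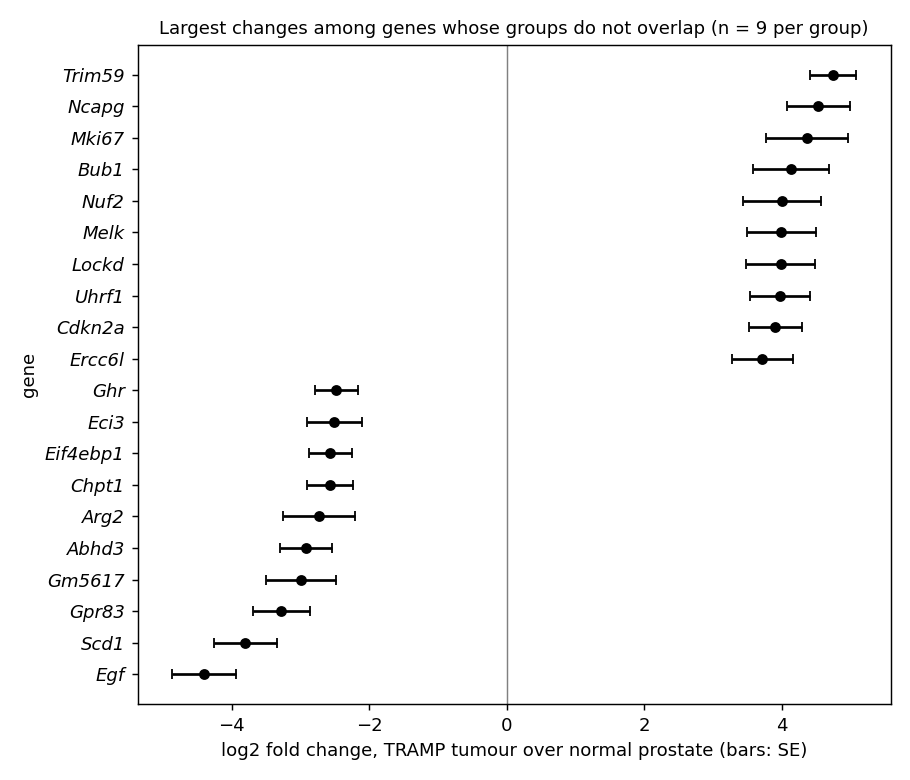
Log2 fold change of TRAMP tumour over normal prostate (x axis) for the 10 largest rises and 10 largest falls among genes whose groups did not overlap, with bars for the SE and 9 arrays per group. Trim59 stands at 4.75 and Egf at -4.41; fold changes of genes dim on all normal arrays are not bounds.

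Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01. It called 13 of 33 lists, 9 up and 4 down. That number is no larger than chance gives: 28 of 100 splits of the arrays, the real one included, called as many, and the other splits called a median of 10. With an estimated correlation none of the 33 was called, the smallest adjusted p being 0.262. An exact two-sided permutation test of each list's mean score over all splits of the arrays, added after this was seen, called 15 lists, 11 of them among the 13. The exact test asks whether a list's score differed between the groups at all, while camera compares the list with the other genes. A call by one is therefore no check on a call by the other. The same 100 splits were also counted for each list alone, as given beside it.

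The mitosis list rose, with 18 of 20 measured genes higher, 0 lower and a median log2 fold change of 2.78 (camera adjusted p = 2.71e-15, adjusted p = 0.264 with an estimated correlation). Adjusted over the list alone, 18 were higher and 1 lower. Ccna2, a cyclin of S phase and mitosis, rose by 3.34 ± 0.439 SE, the kinesin Kif11 by 3.335 ± 0.428 SE (floored 2.75), the spindle midzone gene Prc1 by 2.89 ± 0.307 SE and Top2a by 2.50 ± 0.504 SE. Of the DNA replication list, 23 of 26 genes were higher (24 adjusted over the list alone) and 0 lower, with a median of 2.12 (camera adjusted p = 3.84e-20, adjusted p = 0.262 with an estimated correlation). Its helicase subunits Mcm5 and Mcm4 rose by 3.36 ± 0.381 SE and 2.33 ± 0.262 SE, and the licensing factor Cdt1 by 3.001 ± 0.362 SE. Of the DNA repair list, 12 of 15 genes were higher over all genes and adjusted over the list alone (camera adjusted p = 3.26e-09, adjusted p = 0.262 with an estimated correlation). Rad51ap1 rose by 2.90 (floored 2.38), Brca1 by 2.48 (floored 2.22), Chek1 by 2.13 and Exo1 by 1.92 (floored 1.63). For each of these 3 lists the score of every tumour lay above every normal array (exact permutation adjusted p = 0.000271), in both technical batches, and only the real split of 100 gave a camera p as small.

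Regulators of the RB and E2F pathway, which controls entry into S phase, moved mostly upward, with 14 of 22 genes higher and 2 lower (14 and 3 adjusted over the list alone). The camera adjusted p was 2.52e-06, with an adjusted p of 0.262 with an estimated correlation, and again only the real split was as small. E2f7 rose by 2.97 ± 0.368 SE (floored 2.06), Ccne2 by 2.68 ± 0.461 SE and Rbl1 by 1.61 ± 0.261 SE. The cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn1b were also higher, Cdkn1a by 1.21 ± 0.321 SE and Cdkn1b by 1.12 ± 0.224 SE, while Rb1 was 10.11 ± 0.279 in normal prostate and 10.79 ± 0.955 in tumours (limma adjusted p = 0.123). Of the Polycomb and DNA methylation list, 7 of 17 genes were higher over all genes and adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.329 with an estimated correlation), and 4 of 100 splits gave a camera p as small. Hells rose by 1.88, Dnmt1 by 1.87, the histone methyltransferase Ezh2 by 1.80 and Dnmt3a by 0.80. Uhrf1, also on the DNA replication list, had the largest rise in each of them, 3.97. The mean of the Polycomb list, 0.765, lay above its median of 0.402. For the RB and E2F list and the Polycomb list every tumour's score lay above every normal array.

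**Figure D2:**
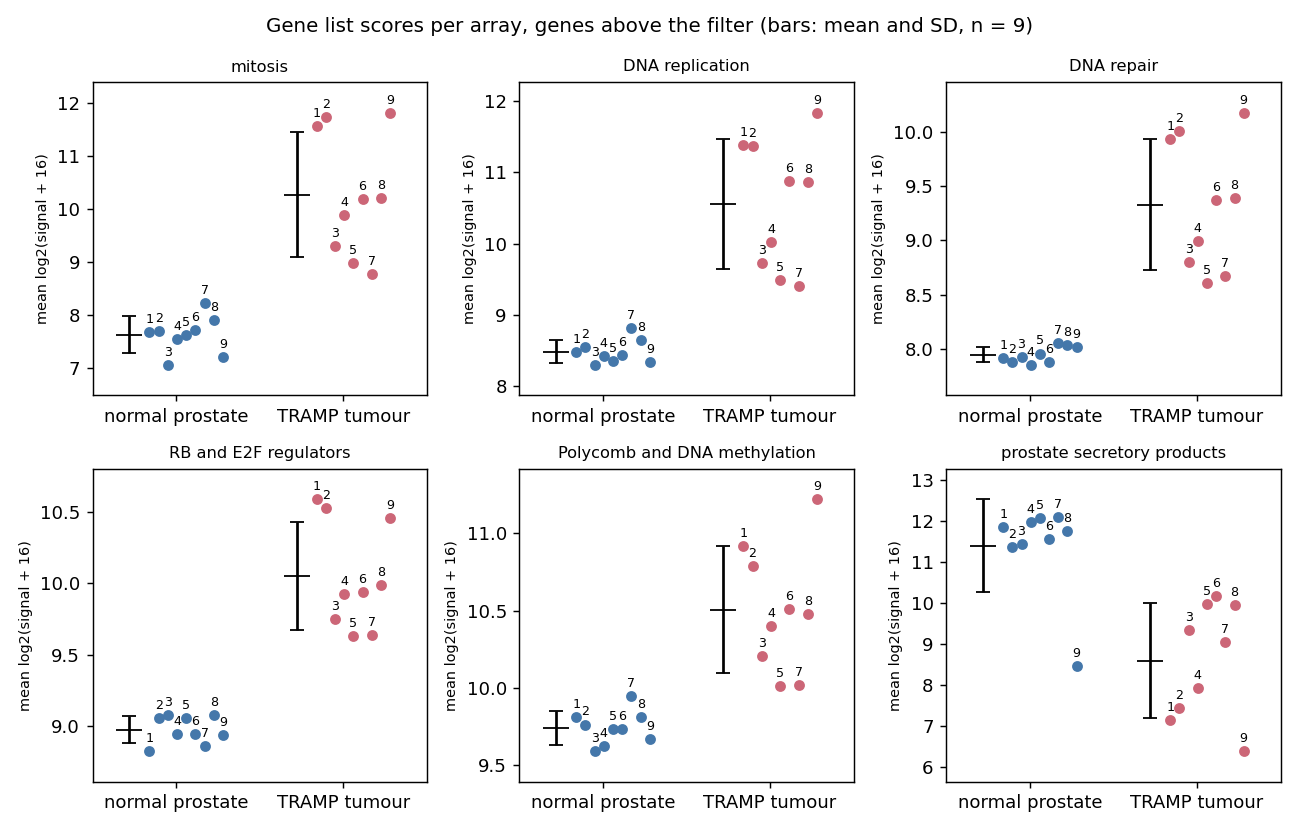
Mean log2(signal + 16) of the measured genes of 6 lists (y axis) on each of 9 normal prostate and 9 TRAMP tumour arrays, numbered by replicate, with bars for the mean and SD. For mitosis the normal arrays average 7.62 and the tumours 10.27, and normal prostate 9 stands apart at 8.47 for prostate secretory products.

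Secreted products of the prostate fell, with 8 of 15 genes lower, 0 higher and a median of -4.08 (camera adjusted p = 3e-04, adjusted p = 0.329 with an estimated correlation); 10 were lower adjusted over the list alone. Only 2 of 100 splits gave a camera p as small. Of the 7 genes not called, Pate4 had the largest rise of the list, 3.16. It measured 15.26, 15.61 and 15.28 in tumours 3, 5 and 7 and 14.78 on normal prostate 9. Pate4 is also on the seminal vesicle list. Cdcp3 fell from 13.21 ± 2.31 to 5.97 ± 0.85 (floored -6.00), Wfdc3 from 13.57 ± 2.41 to 7.35 ± 0.467, Agr2 from 12.15 ± 2.08 to 6.03 ± 1.89 (floored -4.60) and Azgp1, zinc alpha-2-glycoprotein, from 13.97 ± 1.75 to 8.22 ± 1.43. The SDs in normal prostate come largely from normal prostate 9, whose score of 8.47 lay below the next lowest normal array at 11.4. Probasin, Pbsn, did not pass the filter on low values and measured 10.6 ± 3.19 in normal prostate and 4.81 ± 0.736 in tumours. Within the batches the score differed by -3.35 and -1.89. The second of these included normal prostate 9, at 8.47 where normal prostates 7 and 8 stood at 12.11 and 11.76. Androgen-responsive genes included 6 lower and 1 higher of 20, the same adjusted over the list alone. The list did not pass by camera (adjusted p = 0.0726, and 0.369 with an estimated correlation) but did by the exact permutation test (adjusted p = 0.00407). A camera p as small came from 6 of 100 splits. Slc45a3 fell by 2.51 ± 0.539 SE, Fkbp5 by 1.51 ± 0.309 SE and the glucocorticoid-inducible Tsc22d3 by 1.30 ± 0.297 SE.

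Genes of protein folding in the endoplasmic reticulum were lower in 13 of 24 cases and higher in none, or 16 adjusted over the list alone (camera adjusted p = 2.52e-06, adjusted p = 0.502 with an estimated correlation). Creb3l4 fell by 2.26 (floored -1.67), Creld2 by 1.69, Herpud1 by 1.55 and Pdia4 by 1.21. Of the mitochondrial respiration list, 6 of 19 genes were lower over all genes and adjusted over the list alone, with a median of only -0.25 (camera adjusted p = 0.00496, adjusted p = 0.502 with an estimated correlation). Cox4i1 fell by 0.69, Ndufb5 by 0.68 and Sdha by 0.52. All 7 measured adipocyte genes were lower, over all genes and adjusted over the list alone, with a median of -3.78 (camera adjusted p = 2.8e-05, adjusted p = 0.329 with an estimated correlation). Adiponectin, Adipoq, fell from 12.23 ± 2.38 to 6.77 ± 2.13 (floored -4.46) and Retn by 3.05. Cidec and Pck1 were dim on 8 of 9 tumour arrays, with log2 fold changes of -4.50 (floored -2.85) and -4.23 (floored -2.32). Camera p-values as small came from 14, 23 and 8 of 100 splits for these 3 lists, and the exact permutation test gave adjusted p-values of 0.0138, 0.013 and 0.0031. The mitochondrial call was lost under quantile normalization (adjusted p = 0.292).

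Among lists of stromal, invasion and immune genes camera called 4 upward, with few genes passing in each. Over all genes 1444 of 12793 were higher, a larger share than in the interferon list and not far below that in the EMT list. Of the fibroblast and matrix list, 7 of 20 genes were higher, 8 adjusted over the list alone (camera adjusted p = 0.000463, adjusted p = 0.586 with an estimated correlation, exact permutation adjusted p = 0.0486). Col1a1 rose by 1.81 ± 0.348 SE and Thy1 by 1.67 ± 0.4 SE. Of the EMT and invasion list, 3 of 19 were higher, 2 adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.502 with an estimated correlation, exact permutation adjusted p = 0.0165). Timp1 rose by 1.78, Mmp14 by 1.04 and Mmp2 by 0.85. The camera call of the EMT list was lost with the actin ratio as a covariate (adjusted p = 0.0581). It was also lost with seminal vesicle and smooth muscle scores as covariates (camera adjusted p = 0.182). Of the macrophage and myeloid list, 4 of 17 were higher, 6 adjusted over the list alone, and of the interferon list 1 of 17 by both counts. Camera gave these adjusted p-values of 0.00193 and 0.00926 (adjusted p = 0.654 for both with an estimated correlation), but neither passed the exact permutation test (adjusted p = 0.0866 and 0.14). C1qa rose by 1.88, Aif1 by 1.11, Laptm5 and Fcer1g by 1.18, and Oas2 by 1.87 (floored 1.34). Between 21 and 40 of 100 splits gave camera p-values as small for these 4 lists.

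Neuroendocrine genes differed from tumour to tumour. Of the 30 fixed genes 8 passed the filter, with 2 higher, Ncam1 by 2.845 ± 0.553 SE and Cacna1a by 1.16 ± 0.289 SE (floored 0.68; camera adjusted p = 0.0908, exact permutation adjusted p = 0.023, adjusted p = 0.654 with an estimated correlation). Of 100 splits 36 gave a camera p as small. Ncam1 was highest in tumours 9 and 1, at 12.79 and 12.06, but was also high on arrays high in seminal vesicle genes. It stood at 10.91, 11.42 and 11.55 in tumours 3, 5 and 7. On normal prostate 9 it was 11.32, with at most 8.38 on the other normal arrays. Without the filter the list passed by camera (adjusted p = 0.00247). Chromogranin A, Chga, below the filter, measured 6.81 ± 0.592 in normal prostate and 7.81 ± 2.77 in tumours, with 11.5 in tumour 1, 9.996 in tumour 4 and 12.24 in tumour 9. Synaptophysin, Syp, did not pass (7.48 ± 0.38 against 7.88 ± 1.10, limma adjusted p = 0.451). Keratin genes of the luminal and basal epithelium did not pass either: Krt8 was 13.68 ± 0.361 against 12.68 ± 2.39 (limma adjusted p = 0.347) and Krt5 9.55 ± 1.21 against 9.10 ± 1.48 (limma adjusted p = 0.613). The luminal homeobox gene Hoxb13 fell by 3.68 ± 1.31 SE (limma adjusted p = 0.0488), the only 1 of 19 measured luminal genes called. None was called adjusted over the list alone, and its probe set did not pass over all probe sets. Hoxb13 was lowest on the arrays highest in seminal vesicle genes, at 4.39, 4.40 and 4.26 in tumours 3, 5 and 7 and 4.50 on normal prostate 9. In tumours 6 and 8, with seminal vesicle scores of 12.45 and 12.44, it was not low. There it measured 9.736 and 10.15, above tumours 2 and 4 at 7.365 and 9.425. Among tumours it was highest in 1 and 9, at 11.7 and 12.15.

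**Figure D3:**
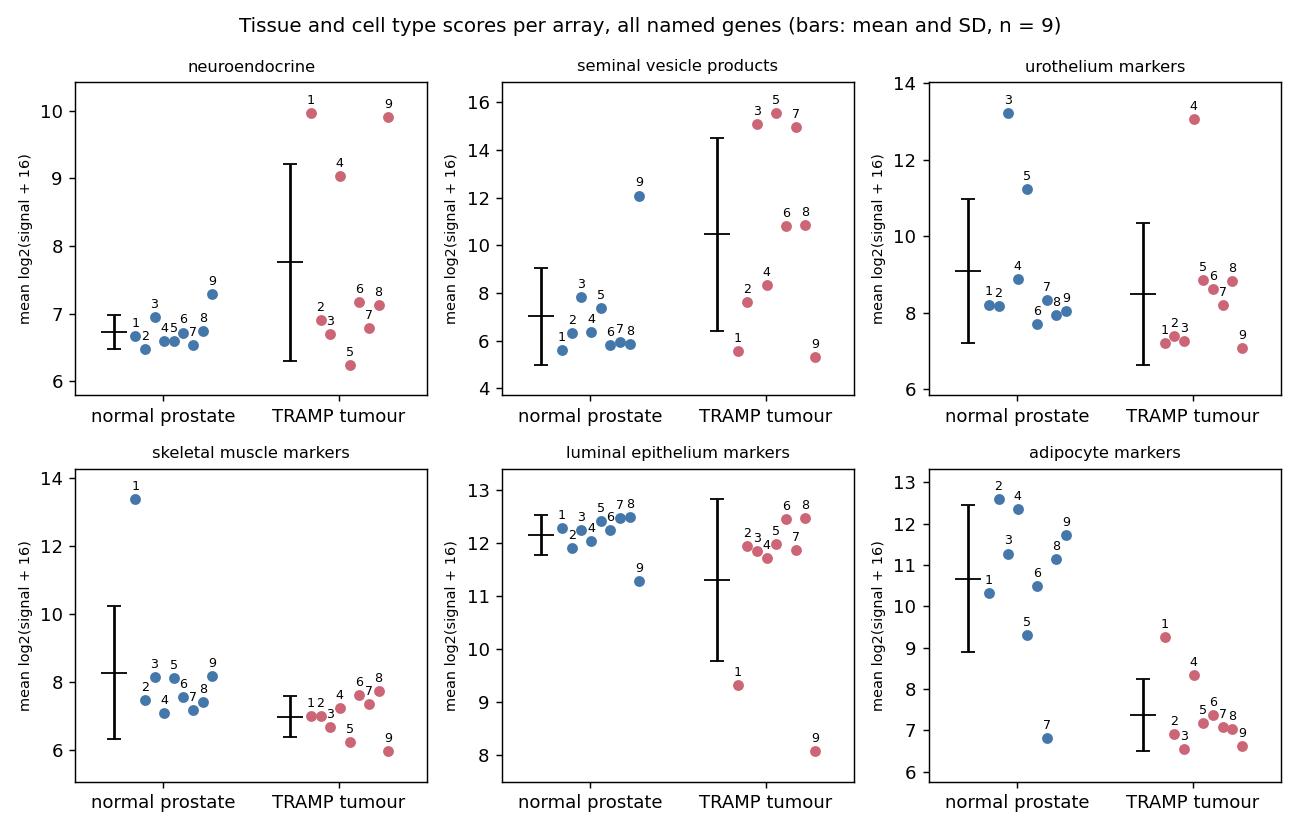
Mean log2(signal + 16) of all named genes of 6 tissue and cell type lists (y axis), without the filter on low values, on each of 9 normal prostate and 9 TRAMP tumour arrays, numbered by replicate, with bars for the mean and SD. Tumours 1, 4 and 9 stand at 9.97, 9.03 and 9.91 for neuroendocrine genes, and normal prostate 9 at 12.09 for seminal vesicle products.

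Markers of neighbouring tissues varied within both groups. The seminal vesicle score rests on 3 measured genes, Svs4, Svs5 and Pate4, the last also on the prostate secretory list. It was 14.08 on normal prostate 9 and 15.23, 15.55 and 15.35 on tumours 3, 5 and 7. It was 12.45 and 12.44 on tumours 6 and 8, and at most 9.27 on the other normal arrays. Without the filter on low values the urothelium score was 13.23 on normal prostate 3, 13.05 on tumour 4 and 11.22 on normal prostate 5, and the skeletal muscle score 13.36 on normal prostate 1. The seminal vesicle list did not pass by camera (adjusted p = 0.126), although its gene Svs4 rose by 4.73 ± 1.66 SE (floored 3.98). Without normal prostate 9 and tumours 3, 5 and 7, 3934 genes were called, and 3613 when normal prostates 1 and 3 and tumour 4 were left out as well, with tumours 6 and 8 kept in both. Without normal prostate 9 and tumours 3, 5, 6, 7 and 8, 4860 genes were called. That fit set 8 normal arrays against 4 tumours, numbers 1, 2, 4 and 9. Tumours 1, 4 and 9 were those high in neuroendocrine genes, so the change in calls also reflects which tumours remained. In that fit the camera calls of the EMT, interferon, macrophage and mitochondrial lists were lost (adjusted p = 0.121, 0.437, 0.121 and 0.567). The luminal epithelium and neuroendocrine lists gained a camera call in it (adjusted p = 0.0111 for both). With all arrays kept, other lists did not pass by camera, among them smooth muscle (adjusted p = 0.968), endothelium (0.834), luminal epithelium (0.176) and basal epithelium (0.854). The same holds for T and NK cells (0.757), B and plasma cells (0.821), MHC class I (0.834) and class II (0.269), skeletal muscle (0.328) and urothelium (0.43). Nerve and Schwann cells gave a camera adjusted p of 0.464 and fatty acid and cholesterol synthesis 0.116. Both passed the exact permutation test (adjusted p = 0.0397), with 31 and 36 of 100 splits as small by camera. With an estimated correlation camera gave an adjusted p of 0.654 for both. In the fatty acid list the largest fall was Scd1, which on normal arrays was high where the adipocyte gene Adipoq was: 15.03 and 15.08 on normal prostates 2 and 4 (Adipoq 14.3 on both) and 12.75 on normal prostate 7 (Adipoq 6.71). The adipocyte list fell, with a median log2 fold change of -3.78. Glycolysis and hypoxia gave 0.179, polyamines 0.43 and p53 targets 0.887. Tumour antigens gave 0.861, with Sox4 higher by 2.37, Kit by 1.89 and Cd276, dim on 8 of 9 normal arrays, by 1.63 (floored 0.76) and Steap1 lower at -1.51, and the housekeeping list 0.887. Median, mean and test differed in sign for the basal epithelium, endothelium, smooth muscle and MHC class I lists. Of the erythroid list 1 gene was measured and no test was run.

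Tumours differed among themselves more than normal arrays did for most genes, with a median SD of 0.513 against 0.365 and a larger SD in tumours for 74.4% of genes. An exact two-sided permutation test of the spread of list scores called 0 of 33 lists after adjustment, with 8 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0611 for DNA repair and DNA replication. That count was unstable: 0 to 6 lists were called when each array was left out in turn. A family of 4 relations between list scores was fixed in advance. Neuroendocrine scores of tumours 1, 4 and 9 lay apart, so relations were computed over the other 6 tumours. Against androgen-responsive genes r was 0.664 (exact permutation p = 0.206) and rho 0.486 (exact permutation p = 0.356), against luminal genes r was 0.643 (p = 0.269, exact permutation) and rho 0.486 (p = 0.356), and against mitosis r was -0.0246 (p = 0.96) and rho 0.0286 (p = 1). Leaving out the 2 arrays farthest from the median, r was 0.414, 0.347 and -0.293. In 6 normal prostates, without 3, 5 and 9, smooth muscle against prostate secretory products gave r = -0.576 (exact permutation p = 0.229), rho = -0.771 (exact permutation p = 0.103) and r = -0.95 without the 2 farthest. The adjusted p of r was 0.359 for 3 relations and 0.96 for mitosis, so none passed. With a filter at the 60th percentile, neuroendocrine against mitosis gave r = -0.976 over the same 6 tumours (exact permutation p = 0.00694, unadjusted). The batches of these clusters hold fewer than 6 arrays and gave no value.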

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

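All tests of explanations in this part were chosen after the values were seen, except the counts of other splits of the arrays. In 388 comparisons of an array with the other 8 of its group, the highest or lowest array stood apart by its gap to the nearest neighbour in 56, where chance gives about 1 in 20, or 19.4. Values of one array are not independent, since the same array was counted for many genes.

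Normal prostate 9 was low in the score of androgen-responsive genes (9.42), luminal epithelium markers (11.3) and prostate secretory products (8.47). It was low in log2 Agr2 (6.95), Azgp1 (9.66), Btg2 (10.3), Ccne2 (6.31), Cdcp3 (7.46), Ehf (10.7), Ezh2 (8.49), Hoxb13 (4.5), Myc (7.84), Slc45a3 (8.92) and Wfdc3 (7.25). Normal prostate 9 was high in the score of seminal vesicle products (14.1). It was high in log2 Eci3 (12.3), Igtp (9.9), Ncam1 (11.3), Pate4 (14.8) and Svs5 (15). Normal prostate 7 was low in the score of B cell and plasma cell markers (7.08), glycolysis and hypoxia (10.2) and p53 targets (9.45). It was low in log2 Adipoq (6.71), Ighm (5.14) and Plk2 (6.09). It was high in the percent of signal in the 10 brightest probe sets (2.08) and the log2 hybridization controls (13.1). It was high in log2 Chek1 (8.53). Normal prostate 1 was high in the score of skeletal muscle markers (13.8). It was high in log2 Ccng1 (13). Normal prostate 4 was low in log2 Cdkn2a (4.56) and Dnmt3a (9.32). Normal prostate 8 was high in log2 Ncapg (6.2). Normal prostate 3 was high in log2 Rbl1 (9.2) and Trp63 (12).

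TRAMP tumour 9 was low in the score of fibroblast and matrix markers (9.33) and MHC class II presentation (8.94). It was low in log2 Cald1 (10.5), Fn1 (10.1), H2-Aa (9.93), H2-Eb1 (8.59) and Mmp14 (8.63). TRAMP tumour 2 was low in log2 Pmp22 (9.25) and Tsc22d3 (8.67). TRAMP tumour 2 was high in the score of glycolysis and hypoxia (12.3). It was high in log2 Myh1 (8.38). TRAMP tumour 4 was high in the score of urothelium markers (13.3). It was high in log2 Krt5 (12.4), Upk1a (13.1) and Upk2 (13.4). TRAMP tumour 3 was low in log2 Cd276 (6.84) and Cdkn1a (8.84). TRAMP tumour 1 was high in log2 Cidec (8.24), Pck1 (7.41) and Retn (10.6).

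Normal prostate 9 was low in prostate secretory products and high in seminal vesicle products. A tumour array under a normal label is argued against by its mitosis score of 7.21, below the highest of the other 8 normal prostates at 8.22. Poor RNA on this array is argued against by its actin 3' to 5' log2 ratio of 0.314, the lowest of the normal prostates, whose highest was 2.48. A sample made mostly of seminal vesicle in place of prostate lobes stays open, with no test on genes apart from the pattern itself, as does a swap with a sample from outside the series. Without the filter on low values its seminal vesicle score was 12.09, against 15.08, 15.57 and 14.98 on tumours 3, 5 and 7. On every normal array, this one included, Svs3a and Svs6 lay at least 8.37 and 6.71 below tumour 5. No array of normal seminal vesicle is labelled in the series, so these values do not decide it.

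Tumours 3, 5 and 7 had seminal vesicle scores above that of normal prostate 9, and tumours 6 and 8 had intermediate scores. Normal seminal vesicle tissue alone is argued against, since their mitosis scores lay at least 1.56 above normal prostate 9. Tumour tissue in or next to the seminal vesicle and a mixture of both tissues may each give such a profile, and no test here separated them. The design names no dissection site for the tumours.

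The rise of the mitosis and DNA replication lists was set against technical causes. The batches do not account for it: the smaller of the 2 within-batch mean log2 fold changes of the mitosis list was 2.47. Centred on housekeeping genes the mean was 2.61, and with the actin ratio as a covariate 2.62, which argues against scaling and 3' bias. A biological difference, tumour against normal gland, remains as a hypothesis. Of 100 splits of the arrays, 1, the real one, gave as many genes, 3067 against at most 179 in the others, and 1 gave as many probe sets, 5358 against at most 2. An accident of grouping is therefore not a likely source of these counts. It cannot be excluded for the number of lists called by camera, since 28 of 100 splits called 13 or more, and the highest other split called 19.

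Genes of the fixed lists that did not pass the filter on low values were tested only in the setting without it. In 17 of them the highest tumour lay at least 4 above the highest normal array on the log2 scale. The highest was tumour 5 for Spinkl, Svs3a and Svs6 and tumour 9 for all the others. Each difference therefore describes that tumour and not the tumours as a group. The differences were Ndc80 (4.56), Ttk (4.52), Pole (5.34), E2f8 (4.81), Spinkl (8.18), Chga (4.75), Chgb (7), Insm1 (5.65), Scg3 (5.55), Scg5 (4.97), Ddc (5.75), Snap25 (5.51), Stmn3 (5.84), Elavl4 (6.08), Mycn (4.36), Svs3a (8.37) and Svs6 (6.71). Tumours above the highest normal array numbered 9 for Ndc80, Pole and E2f8, 8 for Ttk and 6 for Spinkl. For the neuroendocrine genes from Chga to Elavl4 they numbered 3 to 5.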

How the results depend on the processing

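Alternatives that used the technical batches, left out arrays high in genes of another tissue, used covariates or permuted list scores were chosen after seeing the data. Of the 3067 genes called, 3058 to 3067 kept their direction in every setting that tested all of them. The exact Wilcoxon test, the intensity trend and the replicate block cannot change a direction. Every setting reused arrays that had picked these genes, so the count is no independent check. For counts, list tests and relations 1661 of 1761 values were unchanged, 33 lost the call, 25 gained one, 42 counts moved and 0 reversed. A list test or relation was unchanged if it kept its direction and its side of the threshold. Counts were judged by a fixed ratio to the main count. By that rule 2109 and 3934 genes against 3067 counted as unchanged, and 1647 and 4860 as moved. A change of sign between values that both missed the threshold was counted as unchanged. For the named genes 5714 of 6195 values were unchanged, 350 lost the call, 130 gained one and 1 reversed. Of 96 named genes past the threshold, 59 kept it in all settings except the batch without poly-A controls. The reversal was Atp5a1, at 0.2243 without probe sets that can match several transcripts against -0.4452, where a different probe set stood for the gene. Low signal limited what was tested: 27292 of 45101 probe sets passed the filter. Values for relations are missing where fewer than 6 arrays remained.

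The replicate numbers are shared by both groups and do not pair the arrays by this check: with group means taken out, 1 of 9 same-numbered pairs correlated over 0.1 (-0.0767 to 0.35), and 2 of 18 arrays matched their own number best. With the numbers as a replicate block 2645 genes were called, 2495 of them shared.

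Lists differing in spread numbered 2 with a pseudocount of 64, quantile normalization, arrays centred on the 75th percentile or standardized scores, against 0. With no filter on low values, the list adjusted p-values were androgen-responsive genes 0.0108, neuroendocrine 0.00247, seminal vesicle products 0.0134 and skeletal muscle 0.0298. With a filter at the 60th percentile 440 genes were higher by 2-fold or more, the neuroendocrine score against the mitosis score over the same 6 TRAMP tumours gave r = -0.976 and the androgen-responsive list passed (adjusted p = 0.0408). Under quantile normalization the mitochondrial respiration list had an adjusted p of 0.292. With arrays centred on housekeeping genes, the counts were probe sets higher 1636 and genes higher 935. With a test against a 2-fold change, the counts were genes higher by 2-fold or more 71 and genes lower by 2-fold or more 40. With an estimated inter-gene correlation, the list adjusted p-values were adipocyte 0.329, DNA repair 0.262, DNA replication 0.262, EMT and invasion 0.502, ER folding and secretion 0.502, fibroblast and matrix 0.586, interferon response 0.654, macrophage and myeloid 0.654, mitochondrial respiration 0.502, mitosis 0.264, Polycomb and DNA methylation 0.329, prostate secretory products 0.329 and RB and E2F regulators 0.262. With fry, the list adjusted p-values were androgen-responsive genes 0.00177, interferon response 0.169 and macrophage and myeloid 0.095. With only the arrays with poly-A controls 1820 probe sets were higher, and the androgen-responsive list passed (adjusted p = 0.0342). With only the arrays without poly-A controls all counts of probe sets and genes were 0. The list adjusted p-values were interferon response 0.11, macrophage and myeloid 0.15, mitochondrial respiration 0.0581, neuroendocrine 0.0228 and prostate secretory products 0.0562. Leaving out normal prostate 9 and tumours 3, 5 and 7, high in seminal vesicle genes, 1041 genes were lower by 2-fold or more, and the list adjusted p-values were mitochondrial respiration 0.157 and neuroendocrine 0.0233. Leaving out normal prostate 9 and tumours 3, 5, 6, 7 and 8 kept 8 normal arrays and 4 tumours. These 4 included tumours 1, 4 and 9, high in neuroendocrine genes. All counts moved, with probe sets changed 9055, higher 4189 and lower 4866. Genes changed numbered 4860, higher 2196 and lower 2664, and by 2-fold or more 1165 higher and 1466 lower. The list adjusted p-values were then EMT and invasion 0.121, interferon response 0.437, luminal epithelium 0.0111, macrophage and myeloid 0.121, mitochondrial respiration 0.567 and neuroendocrine 0.0111. Leaving out 7 arrays high in genes of another tissue, with tumours 6 and 8 kept, 1178 genes were lower by 2-fold or more, and the list adjusted p-values were EMT and invasion 0.0744, mitochondrial respiration 0.263 and neuroendocrine 0.0257. With the actin 3' to 5' ratio as a covariate, the counts were probe sets changed 2569, probe sets higher 1310, probe sets lower 1259, genes changed 1647, genes higher 772, genes lower 875 and genes lower by 2-fold or more 422. The list adjusted p-values were EMT and invasion 0.0581 and smooth muscle 0.0407. With seminal vesicle and smooth muscle scores as covariates, 1042 genes were lower by 2-fold or more, and the list adjusted p-values were EMT and invasion 0.182, interferon response 0.136, luminal epithelium 0.022, macrophage and myeloid 0.34 and neuroendocrine 0.00531. With the exact permutation of list scores, the list adjusted p-values were androgen-responsive genes 0.00407, fatty acid and cholesterol synthesis 0.0397, interferon response 0.14, macrophage and myeloid 0.0866, nerve and Schwann cell 0.0397 and neuroendocrine 0.023.

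Leaving out each array in turn gave 4143 to 6127 for probe sets changed, 2140 to 3128 for probe sets higher, 1994 to 2999 for probe sets lower, 2455 to 3411 for genes changed, 1148 to 1591 for genes higher, 1306 to 1820 for genes lower, 592 to 776 for genes higher by 2-fold or more and 565 to 773 for genes lower by 2-fold or more. Lists differing in spread numbered 0 to 6 against 0. List adjusted p-values ran 0.0289 to 0.104 for androgen-responsive genes, 0.0473 to 0.224 for fatty acid and cholesterol synthesis, 0.0221 to 0.427 for MHC class II presentation, 0.0443 to 0.218 for neuroendocrine and 0.0446 to 0.224 for seminal vesicle products. The androgen-responsive list passed without normal prostate 9 and the neuroendocrine list without TRAMP tumour 3. The fatty acid, MHC class II and seminal vesicle lists passed without TRAMP tumour 9. For all of these changes the cause was not tested.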

Other observations

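Most luminal epithelial genes were low in tumours 1 and 9, seen only after the values were read: for 14 of 19 measured these were the 2 lowest tumours, and the luminal scores were 9.33 and 8.07, with 11.73 or more in the others. Keratin genes of luminal cells measured 9.36 for Krt8 and 9.56 for Krt18 in tumour 1 and 7.72 and 7.05 in tumour 9, where no other tumour lay below 13.65 and 13.73. Krt19 measured 8.62 and 4.38, and E-cadherin, Cdh1, 8.95 and 6.45. The 5 exceptions were Cldn3, Prom1, Foxa1, Cd24a and Hoxb13, of which Foxa1 measured 12.66 and 13.36, Cd24a 14.40 and 14.47 and Hoxb13 11.70 and 12.15, the last above every other tumour. Tumour 4, whose neuroendocrine score of 9.03 lay below 9.97 in tumour 1 and 9.91 in tumour 9, had Krt8 at 13.95 and Cdh1 at 13.44 and had Upk3a at 13.78. Foxa2, a factor of the neuroendocrine list, stood at 11.57 in tumour 2, with no other tumour above 7.74. The homeobox gene Hoxb13 measured 4.39, 4.40 and 4.26 in tumours 3, 5 and 7 and 4.50 in normal prostate 9, and 7.37 to 12.15 in the other tumours. The protease gene Mmp7 stood at 14.89 and 14.56 in tumours 6 and 8.

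Arrays correlated with a median r of 0.912 among normal prostates, 0.813 among tumours and 0.794 between the groups. For 2 arrays the best match lay in the other group: tumour 4 with normal prostate 3 at 0.913, against 0.836 for its best tumour, and normal prostate 9 with tumour 7 at 0.882, against 0.842 for its best normal prostate. Tumours 6 and 8 gave the highest r of all pairs, 0.96, and the labels do not say whether they came from 1 animal.

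The batches allow a partial check of direction, chosen after the result was seen. If chance set the direction of independent genes, about 50% of those called on arrays with poly-A controls would keep it on the other arrays. Of 2109 such genes 2041, or 96.8%, did, with a median ratio of log2 fold changes of 0.759. Genes moved together, with estimated correlations of 0.697 for DNA replication and 0.722 for mitosis. Chance can therefore give shares far from 50%, and the share decides nothing about chance. A limma test of the difference in effect between the batches called 0 genes. At an unadjusted p under 0.05 it gave 292, where 640 would be expected by chance. Between the batches themselves 272 genes differed.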
